A study of Mus musculus with 60 samples.

How the data were processed

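RNA-seq libraries came from 6 tissues (kidney, liver, lung, skeletal muscle, skin and spleen) of 22-month-old mice in 2 arms, with 5 libraries per tissue and arm, 60 in all. One arm, called 4F here, carried 1 copy of a polycistronic cassette encoding the reprogramming factors Oct4, Sox2, Klf4 and c-Myc and 1 copy of the rtTA transactivator at the Rosa26 locus, on a C57BL/6 background. Per the series' design text these mice drank doxycycline at 1 mg/ml, which induces the cassette, for 2 days in each week with 5 days of withdrawal, for 7 months from 15 to 22 months of age, and the controls were untreated C57BL/6 mice of 22 months. The treatment protocol on the control samples repeats the doxycycline wording, which goes against that text; the design text was followed, and the labels leave open whether control mice drank doxycycline. The arms differ in genotype and in treatment together, so an effect of the cassette, of rtTA, of doxycycline or of breeding cannot be separated by these samples. The fits held no record of feeding state or hour of collection, so a difference between the arms in these was not tested. The series title speaks of age-associated changes; libraries of young mice were not analysed here, so no direction of change with age is given.

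Total RNA was extracted with a Qiagen RNeasy kit and libraries were made with the Illumina TruSeq Stranded Total RNA kit, per the labels' protocols. The authors deposited raw counts, whole numbers of reads per Ensembl gene ID with 1 column per library, and the 60 single-library files held the same values as the columns of the deposited table of 52636 genes. The genome build was GRCm38, per the submitters' processing notes; the aligner, the counter, the annotation release and whether counting used the strand are not given in the sources used here. Antisense genes, pseudogenes, immunoglobulin segments and genes with close paralogs (Mup, Serpina3, H2, Zfp, Hist1h1, Apol11 and Ighv names among them) are therefore uncertain where reads of a partner gene could be shared. Gene symbols, biotypes and positions were taken from GENCODE M21 on GRCm38, which held 52489 of the gene IDs; the other 147 took 0.008% of the counts and stayed in the tests. Coordinates are 1-based on GRCm38.

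Library totals ran from 16.8 to 39.1 M counts (median 27.6 M). At 20 M counts, 1 CPM is 20 counts, so counting error is small for most of the genes named and the spread between mice sets the precision. Values called at least N-fold are set against a floor of 3 counts over all libraries of the group at 0, and cover counting error only. Within groups, the counts of the 120 pairs of libraries differed by more than sampling noise in every pair (chi-square per degree of freedom 10.1 or more, median 105.6), so no library was treated as a duplicate. Labels call the libraries separate samples with their own numbers but do not say which tissues came from the same mouse, and no number occurs in more than 1 group, so libraries were treated as independent in the main fits; p-values measure the spread between these libraries.

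Each tissue was fitted on its own with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr with a minimum count of 10 and a minimum total count of 15, glmQLFit with robust dispersion, glmQLFTest), with terms for labelled sex and for the arm. Adjusted p-values are Benjamini-Hochberg values from this test over the genes tested in that tissue, and genes under 0.05 are called. Log2 fold changes are 4F minus control with labelled sex held fixed. They are given ± an error, the size of the fold change over the square root of the test's F statistic. This error is derived from the test, so it is no evidence beyond the p-value. Levels are in CPM, counts scaled to the library total, given as mean ± SD over the 5 libraries of a group. Since sex is a term of the fit, a fitted change can differ from the ratio of the mean levels.

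Sex was checked before the fits from Xist, which is expressed from the inactive X chromosome of females, and from the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. In 12 of the 60 libraries, 2 control libraries labelled male in each tissue, Xist stood at 279 to 1702 CPM and the Y-linked sum at 0.732 CPM or less. Other libraries labelled male had at most 0.482 CPM of Xist and at least 134 CPM of Y-linked transcripts, and libraries labelled female had 263 to 1945 CPM of Xist. The labels give 2 males and 3 females among 4F mice and 4 males and 1 female among controls in each tissue; by transcripts both arms hold 2 males and 3 females. The fit with labelled sex was fixed before the data were examined and is kept as the main one. Its fold changes can be biased for genes that differ between the sexes. After the data were seen, the fits were repeated with sex read from transcripts and with the 12 contradicted libraries left out. This covered the counts of called genes, of called lists and of genes called in several tissues. The count of genes that differed between tissues was repeated with sex read from transcripts but not without those libraries. Genes called under both codings of sex are given first. A library is called male or female below only as labelled.

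The 53 gene lists (30 tested in every tissue, the others in 1 tissue) and the rule for named genes were written before the data were examined; 1245 of 1249 list members were matched, and a list needed at least 3 members tested. Lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 198 tests of a list in a tissue, then with an estimated correlation and with fry. With an estimated correlation none of the 198 tests passed (smallest adjusted p = 0.636), and none passed with fry (smallest adjusted p = 0.106), so each list call below holds only at the preset correlation. Members are counted as called over all genes tested and as called when adjusted over the list alone. Named per tissue were the 10 called genes with the largest rise and the 10 with the largest fall at a mean level over 0 log2 CPM, without provisional, pseudogene or immunoglobulin and T cell receptor segment names; up to 4 called members of each list, or the 2 members of smallest p where a called list had none; the cassette's 4 factors, Nnt and Gt(ROSA)26Sor; genes called with 1 sign in 3 or more tissues; and up to 10 genes called in opposite directions in 2 tissues. Names outside this rule are said to be chosen after their values were seen.

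A joint edgeR fit of all 60 libraries, with sex within tissue, tested whether the difference between the arms differed between tissues (an F test of 5 contrasts). It estimates 1 spread per gene for all tissues together. Calls shared between tissues were counted by sign and set beside the number that independent lists would share. Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no low-count filter, a filter of 1 CPM in 5 libraries, no sex term, males only, no robust dispersion, 1 fit of all tissues, and leaving out each library in turn. The fits were tested on counts simulated from each tissue's means, library totals and spread, with 200 changed genes per comparison, 1 in 2 of them changed 2-fold and the others 4-fold, and without an effect of sex. At 4-fold, 88% were recovered in kidney, 78% in liver, 84% in lung, 84% in muscle, 39% in skin and 82% in spleen, and at 2-fold 72%, 42%, 57%, 43%, 2% and 33% in the same order. For genes raised in kidney alone, the test of the difference between tissues recovered 76% at 4-fold and 31% at 2-fold. Its counts were simulated with 1 spread per gene for all tissues, so an error from pooling the tissues could not show. Some genes that entered the fits and the counts of calls are not reported here by name. Figures were drawn with matplotlib 3.10.9.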

Results

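No factor of the cassette was called in any tissue by edgeR with labelled sex. Pou5f1, the gene of Oct4, averaged at most 0.0158 CPM in the 4F groups and was tested in no tissue. Sox2 was tested only in lung, where it stood at 17.5 ± 1.5 CPM against 17.4 ± 3.02 (adjusted p = 0.947). Klf4 and Myc were expressed in every tissue. The lowest adjusted p of Klf4 was in liver, where it was lower in 4F (-0.94 ± 0.30, adjusted p = 0.123). Myc was higher in 4F spleen without passing (0.59 ± 0.19, adjusted p = 0.0784), and passed by DESeq2 (adjusted p = 0.037) and without Spleen_4F_6525 (adjusted p = 0.0181), but not without Spleen_4F_6526 (adjusted p = 0.311) or with sex read from transcripts (adjusted p = 0.218). It was higher in 4F lung too (1.49 ± 0.51, adjusted p = 0.464), by 0.24 without Lung_4F_6566. Reads of the cassette outside the annotated exons of these genes are not in the counts. Gt(ROSA)26Sor is a transcript of the Rosa26 locus (chromosome 6, 113067428 to 113077333), with antisense as its annotated biotype. Since 4F mice carry rtTA at that locus, a change in its level cannot be told apart from an effect of the insertion. Gt(ROSA)26Sor fell in lung, to 9.67 ± 0.889 CPM against 19.5 ± 1.66 (-0.98 ± 0.11, adjusted p = 0.0199), and in kidney (-1.13 ± 0.17, adjusted p = 0.0323). Its 4F mean was lower in the other tissues too, without passing (adjusted p = 0.0722 in liver, 0.099 in muscle, 0.304 in skin and 0.0589 in spleen). Nnt, which some C57BL/6 substrains lack in part, was called in no tissue. Its level was low in lung (0.363 CPM in 4F against 0.319), muscle (0.665 against 0.197) and skin (0.526 against 0.231), so these tests say little.

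Genes called under both codings of sex numbered 95 in kidney, 243 in liver, 19 in lung, 3 in muscle, 8 in skin and 60 in spleen. With labelled sex the counts were 99, 299, 19, 3, 10 and 1205 in the same order, and with sex read from transcripts 607, 529, 29, 19, 12 and 61. Of the 198 list tests, 86 passed at the preset correlation, 38 higher and 48 lower in 4F. None passed with an estimated correlation (smallest adjusted p = 0.636) or with fry (smallest adjusted p = 0.106). Random splits of the same libraries called as many lists in 63 of 100 cases, the real split included. The medians of lists are therefore given as measured values, and the account of each tissue rests on single genes. The median, the mean and the test had the same sign for each list given below.

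**Figure D1:**
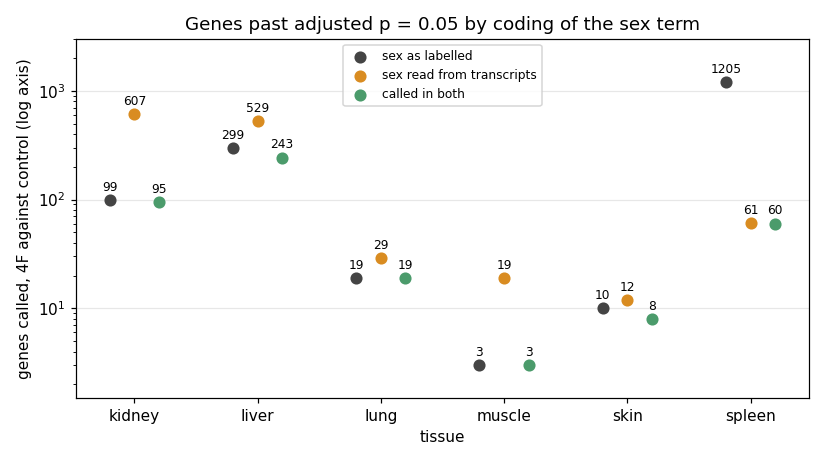
Genes called between 4F and control libraries (log axis) in each tissue, as points for sex as labelled, for sex read from transcripts and for both. Spleen has 1205, 61 and 60 genes, while lung has 19, 29 and 19.

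In 4F kidney, counts of the IgA heavy chain rose and those of the IgM heavy chain fell. Igha, the constant region of the IgA heavy chain, stood at 593 ± 165 CPM against 74.1 ± 31.1 (log2 fold change 3.23 ± 0.34, adjusted p = 0.00729). Each group had 5 libraries, here and below. Jchain, which joins polymeric IgA and IgM, rose as well (1.44 ± 0.25, adjusted p = 0.0474). Ighm, the IgM heavy chain, fell from 509 to 88.9 CPM (-2.81 ± 0.47, adjusted p = 0.0409). Mfap4, a protein of elastic fibres, fell (-1.90 ± 0.28, adjusted p = 0.0289), as did Loxl1, which crosslinks elastin (-0.75 ± 0.13, adjusted p = 0.0486). Antxr1, a receptor that binds collagen, fell from 11.5 to 4.59 CPM (adjusted p = 0.0142). The cytokine Lif (-1.79 ± 0.32) and the sphingosine kinase Sphk1 (-0.85 ± 0.10) fell, with adjusted p of 0.0486 and 0.00737. The metallothionein Mt2 (-0.80 ± 0.15) and the spindle protein Psrc1 (-1.68 ± 0.27) fell too, with adjusted p of 0.0492 and 0.0381.

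Nell2, a secreted glycoprotein, rose in kidney (3.71 ± 0.66, adjusted p = 0.0486), as did the zinc finger gene Zfp457 (3.53 ± 0.42, adjusted p = 0.00825) and the membrane protease Tmprss4 (1.72 ± 0.29, adjusted p = 0.0409). Wdfy1, an adaptor of Toll-like receptor signalling listed in advance as a marker of strain background, rose (1.68 ± 0.19, adjusted p = 0.00737). The clock factor Arntl2 rose as well (1.53 ± 0.28, adjusted p = 0.0492). The acetyltransferase gene Nat8f7 (1.37 ± 0.22) and Apoc3, an inhibitor of lipoprotein lipase (1.21 ± 0.20), had adjusted p of 0.0354 and 0.0381. Kdr, a receptor for VEGF, rose from 89.5 to 112 CPM (adjusted p = 0.0289). Cpt1a, which admits fatty acids to mitochondria, rose from 538 to 640.4 CPM (adjusted p = 0.0486). The lipoprotein receptor Vldlr was called higher with labelled sex (0.34 ± 0.06, adjusted p = 0.0486) but not with sex read from transcripts (0.22 ± 0.05, adjusted p = 0.0556). The pigment cell gene Lrmda (-2.49 ± 0.21) and the interferon-inducible gene Ifi208 (-3.40 ± 0.53) fell at adjusted p of 0.00195 and 0.0343. The secreted protein Scube1 (-1.71 ± 0.22), the leukotriene hydroxylase Cyp4f18 (-1.44 ± 0.24) and Ptprn2 of secretory granules (-1.41 ± 0.25) fell as well. Each called gene lay beyond the control mean in all 5 4F libraries.

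Of 32 fibrillar matrix genes tested in kidney, 2 were called lower over all genes and 18 when adjusted over the list alone. Median log2 fold changes were below 0 for fibrillar matrix (median -0.62), tubule injury (median -0.40), antigen presentation (median -0.36), T and NK cell markers (median -0.62) and interferon-stimulated genes (median -0.39). Their adjusted p with an estimated correlation were 0.636, 0.636, 0.712, 0.733 and 0.813 in that order. No member of the last 4 was called over all genes by edgeR, where 3131 genes of the tissue had an unadjusted p under 0.05, DESeq2 called 1071 and limma-voom 119. Adjusted over the list alone, 5, 10, 6 and 0 of them were lower. Among them Lcn2, a marker of tubule injury, had -2.06 ± 0.44, adjusted p = 0.0727. Medians were also below 0 for inflammatory cytokines (median -0.40), macrophage markers (median -0.42), cell division (median -0.40), senescence and secretory genes (median -0.64), p53 targets (median -0.24) and smooth muscle (median -0.22). An estimated correlation gave adjusted p of 0.764, 0.839, 0.705, 0.705, 0.636 and 0.636 in that order. Medians were above 0 for proximal tubule genes (median 0.28), clock genes (median 0.51), fatty acid oxidation (median 0.14), oxidative phosphorylation (median 0.09) and erythroid markers (median 0.57). Tested with an estimated correlation, adjusted p were 0.636, 0.705, 0.839, 0.88 and 0.636 in that order. Pck1, an enzyme of gluconeogenesis in the proximal tubule, had 1.47 ± 0.27, adjusted p = 0.0528.

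With labelled sex edgeR called 99 of 17231 genes in kidney, 56 higher and 43 lower. Reading sex from transcripts, it called 607, 357 higher and 250 lower, 95 of them shared. Of the 4F libraries, leaving out 1 gave 32 genes without Kidney_4F_6535, 158 without Kidney_4F_6536, 62 without Kidney_4F_6538 and 43 without Kidney_4F_6539. Of the controls, it gave 33 genes without Kidney_Control_6530, 32 without Kidney_Control_6531, 36 without Kidney_Control_6532, 31 without Kidney_Control_6533 and 47 without Kidney_Control_6534. Of the 34 called genes in kidney that the naming rule picked, 33 were called with sex read from transcripts, 26 without a sex term and 8 whichever library was left out. Without that term the adjusted p rose above 0.05 for genes named above, among them Cpt1a (0.258), Scube1 (0.216), Mfap4 (0.0959), Ptprn2 (0.0827), Arntl2 (0.0645) and Loxl1 (0.0581).

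In 4F liver, 4 of 30 fatty acid oxidation genes were called higher and 4 of 31 fibrillar matrix genes lower, and neither list passed with an estimated correlation (adjusted p = 0.636). Ppara, the transcription factor that drives fatty acid oxidation, rose from 75.2 to 156 CPM (0.99 ± 0.19, adjusted p = 0.0385). Of its targets, Angptl4 inhibits lipoprotein lipase and rose (1.54 ± 0.30, adjusted p = 0.0377), and Slc25a20, the carnitine carrier of mitochondria, rose too (1.05 ± 0.21, adjusted p = 0.0398). The fatty acid binding protein Fabp1 rose (0.86 ± 0.19, adjusted p = 0.0497). Apoa4, an apolipoprotein, stood at 458 ± 159 CPM against 82.1 ± 9.04 (adjusted p = 0.00106). Plin4, a lipid droplet protein, rose (3.11 ± 0.63, adjusted p = 0.0434), while Pnpla3, a lipid droplet hydrolase induced by feeding, fell (-4.37 ± 0.85, adjusted p = 0.042). Whether the arms differed in feeding or in hour of collection was not tested. Col1a1, a chain of type I collagen, fell from 10.7 to 2.00 CPM (-2.62 ± 0.46, adjusted p = 0.033). Col1a2 and Col6a3, other collagen chains, fell at adjusted p of 0.033 and 0.0365, and Loxl1 at 0.00971.

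Some chemokines for monocytes and T cells fell in liver, namely Ccl2 (-2.19 ± 0.39, adjusted p = 0.033) and Cxcl9 (-1.85 ± 0.30, adjusted p = 0.0279). Cxcl10 fell from 5.94 to 2.52 CPM (adjusted p = 0.0388). Ciita, the regulator of class II antigen presentation, fell (-1.62 ± 0.21, adjusted p = 0.0109). The class II genes H2-Aa, H2-Ab1 and H2-Eb1 were called lower with labelled sex (-1.51 ± 0.26, -1.51 ± 0.26 and -1.51 ± 0.26) but not with sex read from transcripts, where the folds were smaller and their errors larger (-1.19 ± 0.39, -1.20 ± 0.36 and -1.18 ± 0.38; adjusted p = 0.122, 0.102 and 0.119). Calls were lost too for the macrophage receptors Trem2 (-2.49 ± 0.48, then -2.08 ± 0.61) and Cx3cr1 (-1.54 ± 0.32, then -1.35 ± 0.33) and the endothelial receptor Robo4 (-0.50 ± 0.11, then -0.44 ± 0.11), with adjusted p of 0.0933, 0.0515 and 0.0526 with sex read from transcripts. Ighm fell (-1.91 ± 0.34, adjusted p = 0.0332). The endothelial genes Sox18 (-0.89 ± 0.16), Mmrn2 (-0.68 ± 0.11) and Esm1 (-2.65 ± 0.45) fell at adjusted p of 0.0324, 0.0234 and 0.0302. Pck2, a mitochondrial enzyme of gluconeogenesis, fell (-1.30 ± 0.24, adjusted p = 0.0332).

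Serpina3c, a serine protease inhibitor, stood at 110.5 ± 92.8 CPM against 0.907 ± 0.115 in liver (7.11 ± 0.55, adjusted p = 0.000999). Cox6b2, a testis form of a cytochrome oxidase subunit, rose (5.53 ± 0.29, adjusted p = 2.32e-05), as did the activin subunit Inhbe (2.48 ± 0.32, adjusted p = 0.0109) and the carboxylesterase Ces1b (2.40 ± 0.30, adjusted p = 0.00971). The adrenergic receptor Adrb3 (2.01 ± 0.29), the acetylcholine receptor subunit Chrna2 (2.49 ± 0.43) and Wdfy1 (1.63 ± 0.14) rose at adjusted p of 0.0171, 0.0302 and 0.00106. Usp2, an output gene of the clock (3.83 ± 0.74), and Mup5, a urinary protein (6.65 ± 1.14), lay above the control mean in 4 of the 5 4F libraries. Their adjusted p were 0.0419 and 0.0332. Eps8l1, an actin regulator, fell (-4.91 ± 0.60, adjusted p = 0.00946), as did the basement membrane chain Col4a3 (-3.30 ± 0.60, adjusted p = 0.0342). Adamtsl1, a matrix protein (-2.67 ± 0.44), Lrmda (-2.90 ± 0.35) and Ifi208 (-3.86 ± 0.51) fell at adjusted p of 0.0266, 0.00946 and 0.0109. Apart from Usp2 and Mup5, each called gene named lay beyond the control mean in all 5 4F libraries.

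Of 30 fatty acid oxidation genes tested in liver, 4 were called higher over all genes and 16 when adjusted over the list alone. With sex read from transcripts the counts were 17 and 26. Of 31 fibrillar matrix genes 4 were called lower, and 13 when adjusted over the list alone. The median was above 0 for fatty acid oxidation (median 0.60). Adjusted p was 0.636 with an estimated correlation. Medians were below 0 for fibrillar matrix (median -0.73), antigen presentation (median -0.47), interferon-stimulated genes (median -0.67), macrophage markers (median -0.78), inflammatory cytokines (median -0.78) and endothelial markers (median -0.26). Their adjusted p with an estimated correlation were 0.636, 0.636, 0.764, 0.712, 0.705 and 0.705 in that order. In those last 5 lists 6, 1, 2, 3 and 3 members were called lower over all genes, and 8, 4, 4, 6 and 5 when adjusted over the list alone. Medians were also below 0 for B cell markers (median -0.80), fatty acid synthesis (median -0.48), cell division (median -0.71), senescence and secretory genes (median -0.66), smooth muscle (median -0.79), T and NK cell markers (median -0.33) and immediate early genes (median -0.46). An estimated correlation gave adjusted p of 0.764, 0.779, 0.839, 0.636, 0.733, 0.841 and 0.839 in that order. Medians were above 0 for clock genes (median 0.85), adipocyte markers (median 0.74), glucocorticoid-responsive genes (median 0.59), oxidative phosphorylation (median 0.18), erythroid markers (median 1.63) and drug and bile acid metabolism (median 0.26). Tested with an estimated correlation, adjusted p were 0.636, 0.636, 0.636, 0.839, 0.712 and 0.839 in that order.

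Lists of genes biased between the sexes in liver depended on how sex was coded. In the fit with labelled sex, 2 controls that read as female by transcripts were coded male. Part of a difference between the sexes thus enters its arm term, so medians of these lists with labelled sex do not measure the arms alone. Male-biased genes had a median of 0.54 with labelled sex and -0.12 with sex read from transcripts. The adjusted p with an estimated correlation was 0.839 for labelled sex. Female-biased genes had -3.46 and -0.37, with an adjusted p of 0.839 for labelled sex with an estimated correlation. edgeR called 299 of 14768 genes with labelled sex, 143 higher and 156 lower. Reading sex from transcripts, it called 529, 313 higher and 216 lower, 243 of them shared. Of the 4F libraries, leaving out 1 gave 51 genes without Liver_4F_6515, 87 without Liver_4F_6516, 474 without Liver_4F_6517, 95 without Liver_4F_6518 and 116 without Liver_4F_6519. Of the controls, it gave 196 genes without Liver_Control_6510, 86 without Liver_Control_6511, 101 without Liver_Control_6512, 58 without Liver_Control_6513 and 52 without Liver_Control_6514. Of the 56 called genes in liver that the naming rule picked, 47 were called with sex read from transcripts, 33 without a sex term and 8 whichever library was left out. Without that term the adjusted p rose above 0.05 for genes named above, among them Mmrn2 (0.119), Pnpla3 (0.104), Ciita (0.103), Mup5 (0.0927), Col4a3 (0.0853), Cxcl10 (0.0685), Cxcl9 (0.0674), Col1a2 (0.0623), Adamtsl1 (0.0577) and Col6a3 (0.0513).

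In lung few genes differed, and most of those differed in other tissues as well. Fbp2, a gluconeogenic enzyme of muscle, stood at 10.1 ± 5.68 CPM against 0.625 ± 0.190 (3.50 ± 0.48, adjusted p = 0.0422). Slc5a9, a sugar transporter (1.52 ± 0.22, adjusted p = 0.049), and the zinc finger gene Zfp791 (1.02 ± 0.13, adjusted p = 0.038) rose. Lrmda (-2.37 ± 0.23, adjusted p = 0.00493) and Zfp874a (-0.82 ± 0.11, adjusted p = 0.0435) fell, as did Rsl1, a zinc finger repressor of sex-biased liver genes (-1.31 ± 0.18, adjusted p = 0.0422). The antisense gene BC018473 rose from 0.0479 to 93.8 CPM (adjusted p = 9.95e-05). All 19 called genes, 15 higher and 4 lower of 17861 tested, were also called with sex read from transcripts, which called 29. Each named gene lay beyond the control mean in all 5 4F libraries.

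No member of a list described in lung was called over all genes by edgeR, where 1610 genes had an unadjusted p under 0.05. DESeq2 called 216 genes and limma-voom 19. In lung, medians were above 0 for erythroid markers (median 1.51), adipocyte markers (median 0.57), clock genes (median 0.28), glucocorticoid-responsive genes (median 0.23) and oxidative phosphorylation (median 0.08). Adjusted p were 0.636, 0.764, 0.712, 0.712 and 0.839 with an estimated correlation in that order. Adjusted over the list alone, 10 of 19 erythroid markers were higher with labelled sex and 0 with sex read from transcripts. Medians were below 0 for B cell markers (median -0.50), airway genes (median -0.17), matrix genes (median -0.12), mitochondrially encoded genes (median -0.15), NRF2 targets (median -0.11) and endothelial markers (median -0.09). Their adjusted p with an estimated correlation were 0.841, 0.839, 0.839, 0.785, 0.839 and 0.839 in that order. A further 3 lists changed the sign of their test without Lung_4F_6566, namely T and NK cell markers (median 0.87), cell division (median 0.32) and alveolar type 1 genes (median -0.20). An estimated correlation gave adjusted p of 0.876, 0.839 and 0.839 in that order. At the preset correlation their adjusted p without that library were 0.000219, 0.869 and 0.716. Of the 4F libraries, leaving out 1 gave 7 genes without Lung_4F_6568 and 7 without Lung_4F_6569. Of the controls, it gave 6 genes without Lung_Control_6560, 7 without Lung_Control_6561, 9 without Lung_Control_6562, 9 without Lung_Control_6563 and 6 without Lung_Control_6564. Of the 15 called genes in lung that the naming rule picked, 15 were called with sex read from transcripts, 15 without a sex term and 5 whichever library was left out. Without the contradicted libraries 2 genes were called.

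In skeletal muscle 3 genes were called, all higher in 4F. Among them, BC018473 rose from 0.00726 to 3.98 CPM (adjusted p = 0.00144). Gm19649, a provisional gene, had 1.48 CPM against no counts and was at least 62.3-fold higher (adjusted p = 0.0377). All 3 were also called with sex read from transcripts, which called 19 of 15258 genes. Each lay above the control mean in all 5 4F libraries.

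No member of a list described in muscle was called over all genes by edgeR, where 1421 genes had an unadjusted p under 0.05. DESeq2 called 325 genes and limma-voom 10. In muscle, medians were above 0 for B cell markers (median 3.92), adipocyte markers (median 2.12), T and NK cell markers (median 1.91), erythroid markers (median 2.74), antigen presentation (median 0.47) and glucocorticoid-responsive genes (median 0.34). Tested with an estimated correlation, adjusted p were 0.636, 0.636, 0.636, 0.636, 0.839 and 0.636 in that order. Adjusted over the list alone, 14 of 21 B cell markers and 10 of 17 adipocyte markers were higher. Ms4a1, the B cell surface protein CD20, had 5.52 ± 1.16, adjusted p = 0.15, and the fat cell hormone Lep 5.69 ± 0.92, adjusted p = 0.0971. Medians were below 0 for slow fibre genes (median -1.64), oxidative phosphorylation (median -0.31), mitochondrially encoded genes (median -0.40), skeletal muscle markers (median -0.26), smooth muscle markers (median -0.31) and fast fibre genes (median -0.21). Adjusted p were 0.636, 0.636, 0.733, 0.712, 0.712 and 0.839 with an estimated correlation in that order. Fast fibre genes changed the sign of their test without the contradicted libraries. Casq2, a calcium store protein of slow fibres, had -1.87 ± 0.59, adjusted p = 0.339. The slow fibre list also held Myh2, a myosin of fast fibres, with -1.63 ± 0.50 and adjusted p = 0.315. Of the 4F libraries, leaving out 1 gave 1 genes without Skeletal_Muscle_4F_6557, 12 without Skeletal_Muscle_4F_6558 and 1 without Skeletal_Muscle_4F_6559. Of the controls, it gave 7 genes without Skeletal_Muscle_Control_6550, 0 without Skeletal_Muscle_Control_6551, 6 without Skeletal_Muscle_Control_6552, 1 without Skeletal_Muscle_Control_6553 and 1 without Skeletal_Muscle_Control_6554. Of the 3 called genes in muscle that the naming rule picked, 3 were called with sex read from transcripts, 3 without a sex term and 0 whichever library was left out. Without Skeletal_Muscle_Control_6551, 1233 genes had an unadjusted p under 0.05, and without the contradicted libraries 1 gene was called.

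In 4F skin 8 genes were called under both codings of sex. Slurp1 and Slurp2, secreted ligands of acetylcholine receptors, fell from 46.6 to 8.03 CPM (-2.52 ± 0.31, adjusted p = 0.04) and from 25.3 to 1.20 CPM (-3.95 ± 0.48, adjusted p = 0.0398). Il1f6, an interleukin 36 cytokine of keratinocytes, fell (-4.46 ± 0.50, adjusted p = 0.0398), as did Rgn, a calcium-binding protein abundant in liver (-3.96 ± 0.46, adjusted p = 0.0398). Plg, the plasminogen gene of liver, was called lower with labelled sex (-4.50 ± 0.55, adjusted p = 0.0398) but not with sex read from transcripts (-3.91 ± 0.58, adjusted p = 0.0772). The same held for the apolipoprotein gene Apof, with -5.10 ± 0.66 and adjusted p = 0.0465, then -4.35 and 0.0772. Alb, the albumin of liver, stood at 38.48 to 473.4 CPM in control skin and at 0.8518 to 11.53 CPM in 4F skin. Apof and Alb were chosen after their values were seen. Wdfy1 (1.15 ± 0.15), BC018473 (8.77 ± 0.78) and Gm19649 (6.71 ± 0.65) rose at adjusted p of 0.0408, 0.0197 and 0.0197. The pseudogene Gm12901 was at least 145.2-fold higher (adjusted p = 0.0398). Apart from Apof and Alb, for which this was not counted, each lay beyond the control mean in all 5 4F libraries.

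No member of a list described in skin was called over all genes by edgeR, where 2450 genes had an unadjusted p under 0.05. DESeq2 called 578 genes and limma-voom 7. Medians were below 0 for keratinocyte genes (median -1.19), T and NK cell markers (median -2.001), B cell markers (median -4.17), immediate early genes (median -0.74), cholesterol synthesis (median -0.42) and antigen presentation (median -0.46). Their adjusted p with an estimated correlation were 0.636, 0.712, 0.813, 0.839, 0.839 and 0.88 in that order. Adjusted over the list alone, 7 of 38 keratinocyte genes were lower. The keratin Krt2 had -2.87 ± 0.74, adjusted p = 0.292. In skin, medians were above 0 for fatty acid oxidation (median 0.98), endothelial markers (median 1.22), adipocyte markers (median 2.18), erythroid markers (median 1.63), mitochondrially encoded genes (median 0.69), oxidative phosphorylation (median 0.51), smooth muscle (median 0.54) and skeletal muscle (median 0.72). An estimated correlation gave adjusted p of 0.636, 0.705, 0.705, 0.636, 0.712, 0.733, 0.705 and 0.839 in that order. Skeletal muscle markers changed the sign of their test without Skin_Control_6544 and in the fit of libraries labelled male. Antigen presentation did so without the contradicted libraries. Of 26 fatty acid oxidation genes 18 were higher and 1 lower when adjusted over the list alone, the lower one being Fabp1, which is abundant in liver (-6.86 ± 1.02, adjusted p = 0.081). Of 19 endothelial markers 11 were higher in the same way.

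With labelled sex 10 of 17470 genes were called in skin, 4 higher and 6 lower, with sex read from transcripts 12, and 8 with both. The fit of libraries labelled male gave 244, with 2 controls among them that read as female by transcripts. The fit without the contradicted libraries gave 0, with 1666 genes at an unadjusted p under 0.05. Of the 4F libraries, leaving out 1 gave 2 genes without Skin_4F_6545, 0 without Skin_4F_6546, 0 without Skin_4F_6547, 0 without Skin_4F_6548 and 1 without Skin_4F_6549. Of the controls, it gave 1 genes without Skin_Control_6540, 6 without Skin_Control_6541, 0 without Skin_Control_6542, 2 without Skin_Control_6543 and 52 without Skin_Control_6544. For the counts of 0, unadjusted p under 0.05 numbered 1378 without Skin_4F_6546, 3078 without Skin_4F_6547, 3139 without Skin_4F_6548 and 1607 without Skin_Control_6542. Of the 9 called genes in skin that the naming rule picked, 8 were called with sex read from transcripts, 7 without a sex term and 0 whichever library was left out. Random splits of the skin libraries called as many genes in 6 of 100 cases, the real split included, so chance was not excluded for this count.

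In spleen 60 genes were called under both codings of sex. Serpina3m, a protease inhibitor (4.72 ± 0.44, adjusted p = 0.0024), and the myosin gene Myo15 (3.99 ± 0.59, adjusted p = 0.0296) rose. The phosphatase Dusp1, an immediate early gene, rose (1.08 ± 0.21, adjusted p = 0.0365). Eps8l1 fell from 23.9 to 0.196 CPM (-6.43 ± 0.47, adjusted p = 0.000428). Lrmda (-3.04 ± 0.43), Ifi208 (-2.14 ± 0.30) and the calcium channel subunit Cacng7 (-1.83 ± 0.23) fell at adjusted p of 0.0257, 0.0256 and 0.0118. The receptor gene Vmn2r96 (-3.06 ± 0.35, adjusted p = 0.00735) and Tagln, an actin-binding protein of smooth muscle (-0.68 ± 0.14, adjusted p = 0.0365), fell as well. Each lay beyond the control mean in all 5 4F libraries.

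In spleen, genes of red cells and of cell division were called higher with labelled sex, and with sex read from transcripts no member of either list was. All 33 cell division genes and 19 of 21 erythroid markers were called higher over all genes, and 33 and 21 when adjusted over the list alone. With sex read from transcripts the counts were 0 and 0 over all genes and again 33 and 21 when adjusted over the list alone. Medians were above 0 for cell division (median 2.11) and erythroid markers (median 3.07). Tested with an estimated correlation, adjusted p was 0.636. Under the other coding of sex the medians were 1.74 and 2.36. Mki67, a marker of dividing cells, stood at 2082 ± 1667 CPM against 508 ± 219 (2.53 ± 0.50, adjusted p = 0.0365, then 2.06 ± 0.56 with sex read from transcripts). The transferrin receptor Tfrc (3.47 ± 0.70), the Rh glycoprotein Rhag (3.38 ± 0.69) and the carbonic anhydrase Car2 (3.14 ± 0.65) rose. So did Erfe, the erythroid hormone that lowers hepcidin (5.33 ± 1.12, with 5.285 to 195.1 CPM in 4F libraries), the cyclins Ccne2 (2.74 ± 0.53) and Ccnb1 (2.55 ± 0.51) and the kinase Cdk1 (2.39 ± 0.46). Rises of these 7 genes were 1.97 (Cdk1) to 3.70 ± 1.19 (Erfe) with sex read from transcripts. Their adjusted p was 0.0365 with labelled sex and 0.138 to 0.143 with sex read from transcripts. The mean log2 CPM of erythroid markers was 8.15 to 11.34 in 4F libraries and 5.89 to 8.26 in controls, and that of cell division genes 6.06 to 8.58 and 4.68 to 5.94. Spleen_4F_6526 was highest in both, and its level of the B cell gene Cd79a, chosen after its values were seen, was the lowest, at 45.08 CPM.

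**Figure D2:**
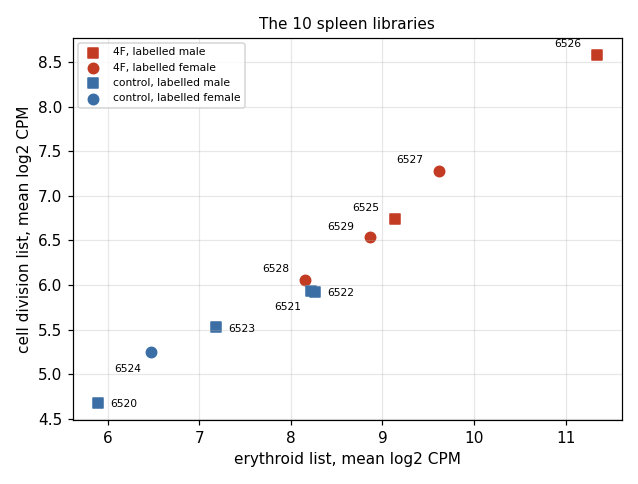
Mean log2 CPM of the cell division list against that of the erythroid list in the 10 spleen libraries, coloured by arm, with squares for libraries labelled male and circles for those labelled female. Spleen_4F_6526 stands at 11.34 on the erythroid axis and 8.58 on the other, and the control libraries end at 8.26 and 5.94.

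Further genes were called higher in spleen with labelled sex only. Asns, which makes asparagine (2.82 ± 0.56), and the amino acid transporter Slc7a5 (1.86 ± 0.44) are targets of the integrated stress response. Gclm (2.30 ± 0.49) and Gclc (1.29 ± 0.31), which make glutathione, and the quinone reductase Nqo1 (2.06 ± 0.50) are targets of NRF2. The antiviral genes Rsad2 (2.64 ± 0.55), Isg15 (2.31 ± 0.55) and Cmpk2 (1.61 ± 0.38) and the RNA sensor Ifih1 (0.88 ± 0.19) were among 5 of 34 interferon-stimulated genes called, and 6 when adjusted over the list alone. Isg15, Cmpk2 and Ifih1 lay above the control mean in 4 of the 5 4F libraries. These genes kept, with sex read from transcripts, rises of 0.75 (Ifih1) to 2.18 (Asns), smaller than with labelled sex and with larger errors, at adjusted p of 0.138 to 0.15. Medians were above 0 for integrated stress response targets (median 0.53), NRF2 targets (median 0.12), interferon-stimulated genes (median 0.07), p53 targets (median 0.03) and oxidative phosphorylation (median 0.48). Adjusted p were 0.839, 0.883, 0.92, 0.994 and 0.824 with an estimated correlation in that order. Of 53 oxidative phosphorylation genes 3 were called higher, and 38 higher and 1 lower when adjusted over the list alone. The cyclin Ccnd1 (-0.73 ± 0.15), the transcription factor Klf2 (-0.80 ± 0.19) and the smooth muscle actin Acta2 (-0.66 ± 0.14) were called lower with labelled sex. They fell about as much with sex read from transcripts (-0.72 ± 0.13, -0.74 ± 0.17 and -0.67 ± 0.13) and were not called (adjusted p = 0.0814, 0.138 and 0.09). Medians were below 0 for smooth muscle (median -0.54), B cell markers (median -0.95), antigen presentation (median -0.28) and endothelial markers (median -0.29). Their adjusted p with an estimated correlation were 0.705, 0.813, 0.839 and 0.839 in that order.

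edgeR called 1205 of 17279 genes in spleen with labelled sex, 1035 higher and 170 lower. Reading sex from transcripts, it called 61, 39 higher and 22 lower, 60 of them shared. Genes at an unadjusted p under 0.05 numbered 5543 with labelled sex and 4173 with sex read from transcripts. limma-voom called 40 and DESeq2 3368. The fit without a sex term called 56, the fit of all genes with any count 58 and the fit without the contradicted libraries 10. Of the 4F libraries, leaving out 1 gave 3739 genes without Spleen_4F_6525, 34 without Spleen_4F_6526, 31 without Spleen_4F_6527 and 27 without Spleen_4F_6529. Of the controls, it gave 27 genes without Spleen_Control_6520, 29 without Spleen_Control_6521, 26 without Spleen_Control_6522, 25 without Spleen_Control_6523 and 10 without Spleen_Control_6524. Of the 63 called genes in spleen that the naming rule picked, 18 were called with sex read from transcripts, 18 without a sex term and 7 whichever library was left out.

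A small set of genes differed in several tissues in the same direction. In all, 62 genes were called with 1 sign in 2 or more tissues and 13 in 3 or more. Shared calls summed over pairs of tissues came to 111, against 13.3 for independent lists. BC018473, an antisense gene on chromosome 11 (116752167 to 116759373), was called higher in 5 tissues. In spleen it stood at 128 ± 54.6 CPM against 0.0608 ± 0.0438. In kidney it was at least 1465-fold higher but was not called (adjusted p = 0.0564). The pseudogene Gm12901 was called higher in 5 tissues, and Gm19649 and the antisense gene A930015D03Rik in 4. Wdfy1, Gm42031, Gm15603, Gm10036 and the immunoglobulin segments Ighv3-2 and Ighv1-14 were called higher in 3 tissues each. Ighv3-2 in spleen stood at 53.6 ± 8.57 CPM against 0.551 ± 0.233. Lrmda (chromosome 14, 22019712 to 23056085) was called lower in 4 tissues, and Ifi208 and Zfp874a in 3 each. The strand used in counting is not given, so levels of antisense genes, pseudogenes and segments are uncertain.

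**Figure D3:**
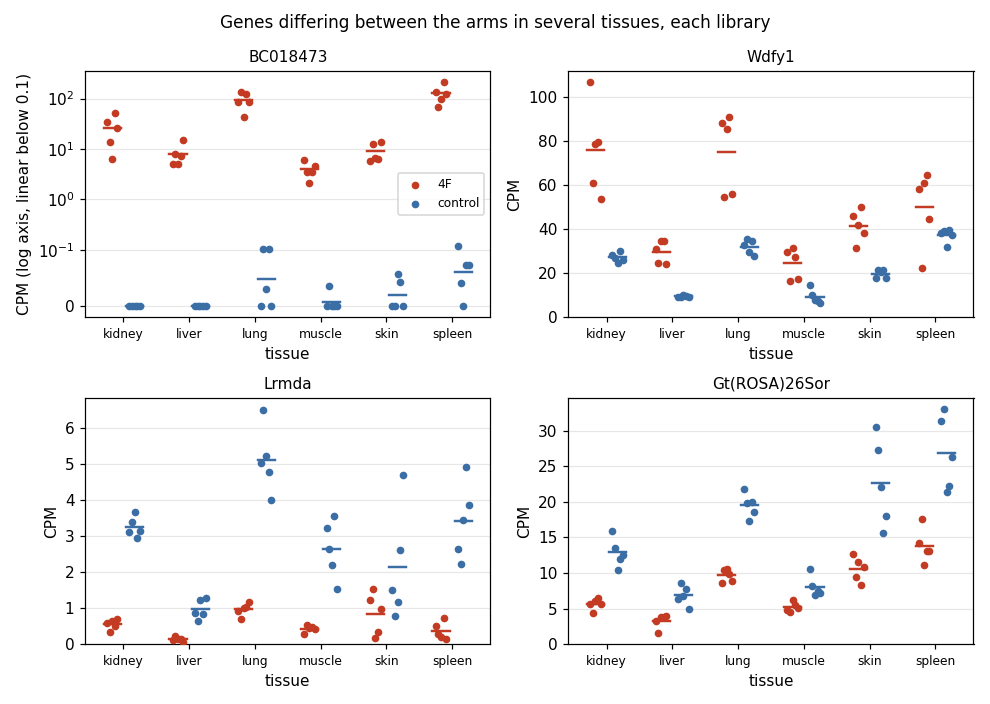
CPM of BC018473 (log axis, linear below 0.1), Wdfy1, Lrmda and Gt(ROSA)26Sor in each library of the 6 tissues, by arm, with bars at the means of 5 libraries. In spleen BC018473 is at most 0.118 CPM in the control libraries and at least 67.97 CPM in the 4F ones.

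With sex read from transcripts 92 genes were called in 2 or more tissues and 24 in 3 or more. Without a sex term the counts were 39 and 22, by DESeq2 762 and 142, and without the contradicted libraries 7 and 2. The labels do not say which tissues came from the same mouse, so the shared calls are not known to be independent.

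The response differed between tissues for 2555 of 21825 genes, and for 2232 with sex read from transcripts, 1683 of them shared. These counts rest on 1 spread per gene for all tissues. With that spread, edgeR called 2842 genes in skin against 10 in the fit of skin alone. In muscle it called 365 against 3, and in kidney 73 against 99. The difference between tissues was not tested with a spread for each tissue. Some genes were called higher in spleen and lower in liver or kidney with labelled sex. For them the difference between the 2 tissues was tested in the fit of all libraries, a test chosen after the first results were seen. Atp2b4, a calcium pump, had -0.90 ± 0.13 in liver and 1.79 ± 0.41 in spleen (difference 2.57 ± 0.39, adjusted p = 7.02e-05). Pola1, a subunit of DNA polymerase alpha, had -0.79 ± 0.17 and 1.80 ± 0.38 (difference 2.47 ± 0.35, adjusted p = 4.51e-05). Rbl1, a repressor of cell cycle genes, had -0.98 ± 0.20 and 1.02 ± 0.25 (difference 1.89 ± 0.35, adjusted p = 0.000693). Sphk1 had -0.85 ± 0.10 in kidney and 1.80 ± 0.39 in spleen (difference 2.54 ± 0.66, adjusted p = 0.018), and Psrc1 -1.68 ± 0.27 and 1.70 ± 0.42 (difference 3.26 ± 0.84, adjusted p = 0.0173). The F test over all 6 tissues also passed for these 5 genes (adjusted p = 0.000168, 0.000224, 0.0045, 0.0142 and 0.0454). For Shcbp1, a protein of cytokinesis, spleen and liver differed (3.67 ± 0.91, adjusted p = 0.01), but the F test did not pass (adjusted p = 0.0638). With sex read from transcripts the 6 differences had adjusted p of 0.00157, 0.000422, 0.00721, 0.0469, 0.0259 and 0.0185. Genes picked because they were called in opposite directions make these tests lenient. None of the 6 spleen rises was called with sex read from transcripts, and the liver falls of Pola1 and Rbl1 were not either (adjusted p = 0.0573 and 0.0724).

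**Figure D4:**
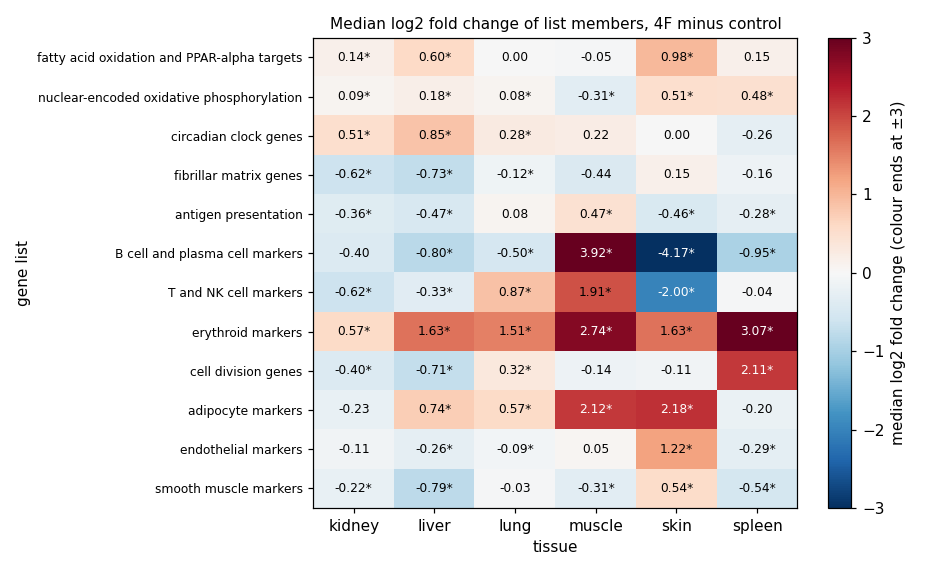
Median log2 fold change (4F minus control, labelled sex) of the members of 12 gene lists in the 6 tissues, with colour ending at 3 on either side and a star for adjusted p under 0.05 by camera at the preset correlation of 0.01. Erythroid markers have medians above 0 in every tissue, from 0.57 in kidney to 3.07 in spleen, and no list passed with an estimated correlation. In each tissue the 4F library whose number ends in 6 had the largest globin share of its group. Without it the erythroid medians were 0.60 in kidney, 0.92 in liver, 0.92 in lung, 0.98 in muscle, 1.05 in skin and 2.23 in spleen.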

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

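The tests of the sex term and of erythroid cells in spleen, the test of neighbouring genes, the tests of genes in 1 tissue against another, and the requirement that the sum of Mup genes pass an exact test were chosen only after the result was seen. Alb in skin was picked for its test after its values were seen too.

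The count of 1205 genes called in spleen with labelled sex was far larger than with sex read from transcripts, where edgeR called 61. A sex term coded from contradicted labels would give such a drop, but the count fell as well with labelled sex kept: to 40 by limma-voom, to 58 without a low-count filter, and to 10 to 34 without Spleen_4F_6526, Spleen_4F_6527, Spleen_4F_6529 or any 1 control. It was 1657 without Spleen_4F_6528 and 3739 without Spleen_4F_6525. The drop is thus not specific to the coding of sex, so that explanation stays open. Genes at an unadjusted p under 0.05 fell far less, from 5543 with labelled sex to 4173 with sex read from transcripts. Median log2 fold changes stayed above 0 with sex read from transcripts, at 2.36 for erythroid markers and 1.74 for cell division genes. The 4F libraries also held more erythroid transcripts, by 2.22 in mean log2 CPM (9.42 ± 1.19 against 7.21 ± 1.05), with a two-sided exact permutation p of 0.0238 for 5 against 5 libraries. Without Spleen_4F_6526 the difference was 1.74 and the exact p 0.0476, and for cell division genes the exact p was 0.0079, the smallest that 5 against 5 can give. Members of both lists were already among the genes called in these libraries, so the permutation test adds no support of its own. A difference in erythroid cells between the arms stays open as well, and the number of single genes called changed with the coding of sex, the method, the filter and the libraries kept.

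The genes that differed in several tissues could come from segments of another mouse strain carried along with the cassette or with rtTA, since such segments would differ in every tissue. A segment around the rtTA locus found no support beyond Gt(ROSA)26Sor itself, which is 1 of the 62 shared genes and was left out as the anchor of the test. Of the other 61, 1 lay within 20 Mb of it, with a Fisher exact p = 1. Elsewhere, 19 of the 61 shared genes had another shared gene within 2 Mb, against a median of 8 in 10000 random draws of tested genes, and 0.008 of the draws had as many. Of these 19, 5 lay in the immunoglobulin heavy chain locus on chromosome 12, where a shared change may also come from B cells. Others were the zinc finger genes Rsl1, Zfp457 and Zfp874a on chromosome 13, which may share reads. The draws took single genes and made no allowance for such clusters, so their share may be too small. Of a list of strain background markers written in advance, Wdfy1 was called higher in kidney, liver and skin and Gt(ROSA)26Sor lower in kidney and lung, while the list passed in no tissue (lowest adjusted p = 0.149 at the preset correlation). Gt(ROSA)26Sor is a transcript of the locus that carries rtTA, so its fall cannot be told apart from an effect of the inserted rtTA. Segments of another strain elsewhere in the genome thus remain a candidate explanation, and a response to the factors was not tested apart from genotype.

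Hepatocyte transcripts were higher in control skin in 26 of 28 list members. Alb was higher in every control than in any 4F library. Its exact permutation p of 0.0079 only restates this, since Alb was chosen after its values were seen. Outside the list, Rgn (3.308 against 0.285 CPM) and Fabp1 (4.291 against 0.04129 CPM), both abundant in liver, were higher in control skin as well. Liver RNA in the control skin libraries would raise all hepatocyte transcripts by a like share of their liver level, and the shares had an upper quartile 2.01 times the lower. A candidate source is therefore liver RNA, with a median share of 0.154% of the liver level. Hepatocyte genes switched on in skin would not need Mup genes to follow, and the share of the liver Mup level was 0.4852 of the list's median, at 3.142 CPM in control and 1.405 CPM in 4F skin. That share met the bound set in advance against this explanation, but with an exact permutation p of 0.1032 for the Mup sum it did not exceed its spread. The explanations cannot be told apart by the Mup genes, and the list's summed level had an exact permutation p of 0.7063.

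Among 216 groups of 5 libraries tested, 27 had a library far from the others by Dixon's ratio, and chance gives about 1 in 20 groups. Myc was low in Kidney_4F_6535 at 4.417 CPM (others 10.7 to 12.84). It was high in Kidney_Control_6530 at 21.59 CPM (others 9.685 to 12.88), in Liver_Control_6510 at 39.46 CPM (others 6.415 to 9.57) and in Lung_4F_6566 at 112.5 CPM (others 13.93 to 21.53). Globin transcripts took 0.1518% of counts in Liver_4F_6516 (others 0.0109 to 0.0424) and 0.0301% in Liver_Control_6511 (others 0.0067 to 0.0103). Lung_4F_6566 also stood high in Ighv1-14 at 10.57 CPM, in Gm42031 at 2.663 CPM and in Ifi208 at 13.77 CPM. Skeletal_Muscle_4F_6558 had a total of 18.43 M counts (others 31.05 to 31.9) and 19610.0 genes detected. Its Nnt level was high, at 1.139 CPM. Spleen_4F_6526 had 22000.0 genes detected, the lowest of its group.

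Genes shared between tissues were high in single libraries. Gm12901 stood at 1.958 CPM in Kidney_4F_6539 and Gm42031 at 1.623 CPM in Kidney_4F_6538 and 5.13 CPM in Spleen_4F_6528. BC018473 stood at 15.32 CPM and Gm10036 at 1.303 CPM in Liver_4F_6519. A930015D03Rik stood at 6.402 CPM in Lung_4F_6567, 2.77 CPM in Skeletal_Muscle_4F_6557 and 6.692 CPM in Skin_4F_6547. Ighv1-14 stood at 18.74 CPM in Skeletal_Muscle_4F_6555, where the other libraries had at most 1.365 CPM. Gm10036 stood at 1.111 CPM in Skeletal_Muscle_4F_6559 and 4.846 CPM in Skin_4F_6549. Ifi208 stood at 1.193 CPM in Skeletal_Muscle_Control_6550. Gm19649 stood at 1.243 CPM in Spleen_Control_6523, where the other controls had at most 0.04018 CPM, and Wdfy1 was low in Spleen_Control_6522 at 31.78 CPM.

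In an F test over all 6 tissues the response differed for Atp2b4 (adjusted p = 0.000168), Pola1 (0.000224) and Rbl1 (0.0045), called in opposite directions in liver and spleen, and for Sphk1 (0.0142) and Psrc1 (0.0454), called so in kidney and spleen. Tested for those 2 tissues alone, the adjusted p were 7.02e-05, 4.51e-05, 0.000693, 0.018 and 0.0173 in that order, lenient for the same reason as the test of lists that follows. Of 33 pairs of tissues in which a list was called in opposite directions, 15 differed with an estimated correlation, and choosing pairs by opposite calls makes that test lenient. What was compared is the change from control to 4F, not the level in a tissue, and each p is for the difference between 2 changes. At an adjusted p of 0.0421 the change of T and NK cell markers was higher in muscle than in kidney and skin, that of cell division genes higher in spleen than in kidney and liver, and that of smooth muscle markers higher in skin than in liver. The same p held for the change of oxidative phosphorylation, higher in skin and spleen than in muscle, for that of mitochondrially encoded genes, higher in skin than in muscle, for that of B cell markers, higher in muscle than in liver, lung and skin, and for that of endothelial markers, higher in skin than in liver and spleen. Endothelial markers differed in their change between skin and lung at 0.0424, and oxidative phosphorylation between liver and muscle at 0.0431.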

How the results depend on the processing

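The fits with sex read from transcripts, without the 12 contradicted libraries and with the replicate block were chosen only after the result was seen. No library number is shared between groups, so the arms could not be paired. Across tissues, libraries of 1 arm with the same last digit deviated together (mean correlation 0.0998 over 150 pairs, 68 of them over 0.1, and 0 of 10000 random draws within tissue, arm and sex as high). A library correlated best with its own digit in 213 of 300 comparisons, a hint from the data that the digit marks a mouse. With the digit as a replicate block, 2505 genes differed between tissues, against 2555 without. The shared calls were not refitted with it, but the random splits kept digits together across tissues. Counting depth limited few of the genes named; the spread between 5 libraries per group set the precision, and the cause was not tested for any count that moved below. With sex as labelled the counts of called genes were 99 in kidney, 299 in liver, 19 in lung, 3 in muscle, 10 in skin and 1205 in spleen.

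DESeq2 called 1071, 1411, 216, 325, 578 and 3368 genes in that order, and 762 in several tissues. Reading sex from transcripts gave 607 in kidney, 529 in liver, 29 in lung, 19 in muscle and 61 in spleen. Leaving out the contradicted libraries gave 25, 33, 2, 1, 0 and 10, and 7 in several tissues, with 1666 genes at an unadjusted p under 0.05 for the 0 of edgeR in skin; this fit has 8 libraries per tissue. The fit of libraries labelled male gave 14, 21, 1, 0, 244 and 6, with 912 genes at an unadjusted p under 0.05 for the 0 of edgeR in muscle. This fit has fewer libraries. In each tissue 2 of its controls read as female by transcripts, so it mixes sex with the arms. Without a low-count filter kidney had 197, muscle 27 and spleen 58, and with a filter of 1 CPM in 5 libraries kidney had 51, lung 11 and muscle 5. Without a sex term lung had 45, muscle 12, spleen 56 and several tissues 39. One fit of all tissues gave 740 in liver, 60 in lung, 365 in muscle, 2842 in skin and 2914 in spleen. limma-voom gave 10 in muscle and 40 in spleen, and the fit without robust dispersion 15 in muscle. RLE size factors moved none of the 8 counts refitted with them by over 1.5 times. The count of genes whose response differed between tissues stayed within 1.5 times under the 5 alternatives run. All 5 kept 1 spread per gene for all tissues, so they do not test that choice.

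Of 86 lists, 0 passed by camera with an estimated correlation (smallest adjusted p = 0.636), 0 by fry (0.106) and 0 with sex read from transcripts and an estimated correlation (0.585). At the preset correlation 78 of the 86 were also called with sex read from transcripts. Some list tests reversed. Without Lung_4F_6566 this held for T and NK cell markers in lung (adjusted p = 0.000219; 4.3e-05 to 0.167 over single libraries left out), cell division genes in lung (0.869; from 1.52e-08) and alveolar type 1 genes in lung (0.716; from 5.01e-05). Without the contradicted libraries it held for fast fibre genes in muscle (0.674) and antigen presentation in skin (0.97). Lastly, skeletal muscle markers in skin reversed with males only (0.801) and without Skin_Control_6544 (0.773; from 1.07e-09 over single libraries left out). No named gene reversed.

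Leaving out 1 library gave 31 (Kidney_Control_6533) to 158 (Kidney_4F_6536) genes in kidney, 51 (Liver_4F_6515) to 474 (Liver_4F_6517) in liver and 6 (Lung_Control_6560) to 25 (Lung_4F_6565) in lung. It gave 0 (Skeletal_Muscle_Control_6551) to 12 (Skeletal_Muscle_4F_6558) in muscle, 0 (Skin_4F_6546) to 52 (Skin_Control_6544) in skin and 10 (Spleen_Control_6524) to 3739 (Spleen_4F_6525) in spleen. Unadjusted p under 0.05 numbered 1233 in muscle and 1378 in skin for these counts of 0 from edgeR. With sex read from transcripts the ranges were 194 to 792, 112 to 946, 7 to 43, 4 to 34, 0 to 11 and 31 to 78, with 1426 genes at an unadjusted p under 0.05 for the 0 in skin without Skin_4F_6549. List calls ran from 81 to 94.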

Other observations

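The tests of random splits were all written before their results were seen; the genes and libraries described first were chosen only after the result was seen.

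Outside kidney, Igha and Ighm differed in sign in some tissues and agreed in others. Igha was higher in 4F liver (1.95 ± 0.45, adjusted p = 0.0527, and 0.0333 with sex read from transcripts), lung (2.21 ± 0.63, adjusted p = 0.391), muscle (3.92 ± 0.96, adjusted p = 0.198) and spleen (1.69 ± 0.87, adjusted p = 0.205). It was lower in skin (-4.72 ± 1.34, adjusted p = 0.304), and Igha passed only in kidney with labelled sex. Ighm was lower in liver (-1.91 ± 0.34, adjusted p = 0.0332), lung (-1.52 ± 0.73, adjusted p = 0.565) and spleen (-0.98 ± 0.48, adjusted p = 0.186). It had the sign of Igha in muscle (1.55 ± 1.15, adjusted p = 0.804) and skin (-2.79 ± 1.56, adjusted p = 0.421). Igkc, the light chain that both classes share, was called in no tissue (adjusted p = 0.321 in kidney). The cell cycle inhibitor Cdkn1a was called in no tissue, with adjusted p from 0.227 in kidney to 0.992 in lung.

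Single libraries stood far from the others in markers of cell types. Ucp1, the uncoupling protein of brown fat, reached 345.2 CPM in Skeletal_Muscle_4F_6557 and at most 0.5015 CPM in the other muscle libraries. Col1a1 reached 953.1 CPM in Skeletal_Muscle_Control_6550 and at most 219.8 CPM in the other muscle libraries. Ighm reached 12110.0 CPM in Skin_Control_6543 and at most 1994 CPM in the other skin libraries. Alb reached 1204 CPM in Lung_Control_6562 and at most 46.44 CPM in the other lung libraries.

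Random splits of the libraries tested whether chance could give as many calls. A bound against chance, on the share of splits that called as many genes, was set in advance. It was met for kidney (1 of 100 splits, the real one, called 99 genes or more, and the highest other called 2). It was met for liver too (1 of 100, with 299 and 2). Lung (3 of 100, with 19 and 1668), muscle (3 of 100, with 3 and 56) and spleen (2 of 100, with 1205 and 8236) met it as well. Skin did not (6 of 100, with 10 and 329). With sex read from transcripts it was met in kidney (1 of 100, with 607 and 1), liver (1 of 100, with 529 and 2) and lung (2 of 100, with 29 and 431). The same held in muscle (2 of 100, with 19 and 103), skin (4 of 100, with 12 and 355) and spleen (1 of 100, with 61 and 1). Genes called in several tissues met it (2 of 100, with 62 and 655), and differences between tissues did too (1 of 24, with 2555 and 1131). For gene lists it was not met (63 of 100, with 86 and 107). Where another split called more genes than the real one, meeting the bound does not exclude chance. In lung, muscle, skin, spleen and several tissues at least 1 split called several times the real count. What such splits share was not examined.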
